A study of Drosophila melanogaster with 26 samples.

How the data were processed

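Fat body RNA of 26 larval samples was measured by sequencing after depletion of ribosomal RNA, per the labels' protocols, which give hand dissection, or shearing followed by centrifugation, as the ways the tissue was obtained. The submitters' processing notes name TopHat 1.3.2, Bowtie 0.12.7 and Cufflinks 1.1.0. Filters and annotation are not given in the sources used here. The table names no unit, and FPKM was assumed when the tests were fixed before the data were examined. The values showed otherwise. The number of features at 1 or above was identical in all libraries of a set, 2402 in run 13-21, 2080 in run 49-54, 2117 in run 55-63 and 2464 in runs 67-76 and 83-92 together. In every library the interpolated 75th percentile equalled 1 when taken over 9608, 8320, 8467 and 9853 features for these 4 sets, with a largest distance from 1 of 2.5e-10, against at least 1.8e-04 for any other feature number tried. The deposited values are thus a ratio, a length-scaled expression value divided by the upper quartile of its library. This was found only after first fits had been seen. The 4 sets were scaled over different features, and in 3 of them over more features than the 9211, 7994 and 9202 above 0 in the libraries used here. Levels are therefore not on a common scale across sets, while diet contrasts within a set compare libraries scaled over the same number of features. Each library still had its own divisor, so a common scale within a set is not assured. In w1118 r4, which lies in 1 set, 165 genes were higher and 48 lower on high sugar, but 85 and 77 after median-of-ratios scaling (limma). The planned filters were kept at their numbers, so that a mean of 1 now stands for about the upper quartile of a library.

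Depth per library is unknown. Over 325 pairs of libraries, at most 1.88 percent of the features below 0.6 shared 1 ratio (within 0.0005 log2 units), so whole reads could not be recovered. Column sums ran from 29779 to 72742 and reflect the scaling. Groups were taken from the titles, and the 26 columns were matched to samples by sucrose level, stock, driver and number. All columns of the table were mapped. Gene symbols are those of the table, with current symbols in parentheses from RefSeq names by locus tag (13055 of 14659 features matched); that annotation is of another build than dm3, named in the submitters' notes, so no coordinates are given.

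Values were taken as log2(value + 1), and the 2428 features with a mean of at least 1 (16.6% of 14659) were tested two-sided with limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The diet effect across backgrounds came from a model with background and diet, and the other contrasts from 6 group means with the spread shared over all 26 samples. All gene-level p values are limma's adjusted p values. Lists of genes (26) and of tissue markers (15) were fixed before the data were examined; 677 of 687 wanted symbols were matched, and the list of male dosage compensation RNAs was not analysed here. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over all lists. For the diet effect across backgrounds 11 lists passed and 0 passed with an estimated correlation. With fry, which asks whether the genes of a list move on balance in 1 direction, 13 passed: these 11, fatty acid synthesis and the sugar-responsive list. In simulated data with the real spread for the diet effect across backgrounds on 2428 genes, limma recovered 71.6% of 67 genes changed by 0.5 log2 units, 95.5% of 67 changed by 1 and 98.5% of 66 changed by 2, and 6.3% of its calls were unchanged genes. In the same simulated data the camera test on 20 genes shifted by 0.5 log2 units gave 1.43e-14, and on 20 genes not shifted it gave 0.663. The simulated genes varied independently of each other, while glycolysis, for 1, had an estimated correlation of 0.398. This check therefore cannot test the preset correlation of 0.01 or the lists that passed with it.

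The genes named for the diet effect were the 12 strongest rises and 12 strongest falls among genes that passed, with a mean of at least 5 in either diet and 1 direction in all 3 backgrounds; a fixed set of metabolic and hormone genes; and up to 4 members of each list with the smallest adjusted p. For each interaction the 5 smallest adjusted p values were named, and for the driver and stock differences the 5 largest changes each way. Alternatives set before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5, median-of-ratios scaling, quantile normalization, robust fits with array weights, no trend, run as a term, an equal-weight mean, leaving out each background, fits on 1 background and leaving out each replicate. Chosen after seeing the data were a common upper quartile over 10094 features, leaving out runs 13-21 and 49-54, averaging the pairs 67 with 83 and 75 with 91, marker means as covariates, run as a term in the interactions, each run on its own contrast, and the rescalings of the list tests of the male stocks. These pairs had correlations of 0.991 and 0.990 but different values, and sampling noise could not be computed without counts, so they were kept as separate samples. Groups share no replicate numbers.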

Results

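RNA from fat body, the organ that stores fat and glycogen in the fly larva, was sequenced from wandering female larvae of Drosophila melanogaster at the last larval stage. Larvae were raised on a control diet with 0.15 M sucrose or on a high-sugar diet with 0.7 M sucrose. The 26 libraries came from 3 backgrounds, each with both diets: w1118 cg (6 control and 6 high-sugar), w1118 r4 (3 and 3) and 60100 r4 (4 and 4). The names give the male parent (w1118, or the stock 60100) and the GAL4 line (cg or r4) that drives transcription in fat body of a transgene for Dicer-2, an enzyme that cuts double-stranded RNA. Replicate numbers fall into 5 runs, 13-21 and 49-54 (both w1118 cg), 55-63 (w1118 r4), and 67-76 and 83-92 (both 60100 r4). Each run holds both diets. Sequencing depth is unknown, since each deposited column had been divided by its own upper quartile. Between 6183 and 8709 of 14659 features had a value above 0 in a library. In w1118 r4 the range was 7124 to 7538 on the control diet and 6183 to 6625 on high sugar. In 60100 r4 it was 8023 to 8709 and 7778 to 8176, and in w1118 cg 7086 to 8040 and 6500 to 8360. Whether depth differed between the diets is unknown. Values below are multiples of the upper quartile of the library, and log2 changes are on the log2(value + 1) scale, which understates the change of genes with low values. The labels do not say that replicates came from separate groups of larvae, so the tests measure only the spread between these samples.

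Dcr-2, which the crosses carry as a transgene, was measured first as a check of the labels. All crosses carry it and the native gene may add to its values, so presence alone does not test the labels. Dcr-2 was present in all 6 groups, with 64.7 ± 12.1 (SD, n = 6) in control w1118 cg, 32.8 ± 16.2 (n = 3) in control w1118 r4 and 23.3 ± 9.57 (n = 4) in control 60100 r4. On high sugar it stood at 19.5 ± 4.07, 14.04 ± 6.35 and 9.80 ± 6.14. The eye colour gene white, mutated in the w1118 stock, stood at 0.403 ± 0.152 in control w1118 cg, 1.23 ± 0.0722 in control w1118 r4 and 2.95 ± 0.628 in control 60100 r4, and at 0.173 ± 0.0639, 1.79 ± 0.137 and 3.60 ± 0.459 on high sugar. Between the 2 backgrounds with w1118 as male parent, which were scaled in separate sets, it differed by -0.96 ± 0.08 (limma, w1118 cg over w1118 r4, averaged over the diets). The RNAs that would check the sex of the larvae were not analysed here.

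The main question of the series was how a high-sugar diet changes the fat body transcriptome. The strongest riser over the 3 backgrounds was CG3348, from 2.60 ± 1.22 (SD, n = 6) to 23.8 ± 5.82 (n = 6) in w1118 cg, from 1.68 ± 0.362 (n = 3) to 34.2 ± 4.33 (n = 3) in w1118 r4 and from 2.03 ± 1.22 (n = 4) to 18.4 ± 1.96 (n = 4) in 60100 r4. Gpdh, glycerol-3-phosphate dehydrogenase, rose by 1.78 ± 0.13 (SE) log2 units, and desat1, which makes monounsaturated fatty acids, by 1.45 ± 0.19. Also among the 12 strongest risers were the cytochrome P450 genes Cyp4e3 (2.28 ± 0.20) and Cyp4d1 (1.62 ± 0.18), CG5773 (1.46 ± 0.19), and the immune-induced peptides IM3 (1.67 ± 0.32), CG15067 (1.76 ± 0.39) and CG15068 (1.58 ± 0.28). In high-sugar w1118 cg, CG15067 stood at 5.31 in replicate 53 and at most at 0.696 in the others. The diet effect differed between backgrounds for CG15067 (limma, joint test, adjusted p = 0.00144), CG15068 (0.0152) and Cyp4e3 (0.0386). CG31775 and CG42586 both rose by 2.34 log2 units with nearly parallel values in every library, so their reads may have been shared. A predicted transcript without a gene symbol rose by 1.89 ± 0.40. The strongest falls were in Act42A, a cytoplasmic actin (-1.55 ± 0.22), CG13335 (-1.54 ± 0.28), the peptidoglycan recognition gene PGRP-SB2 (-1.48 ± 0.53), cib, an actin-binding protein (-1.46 ± 0.36), and Dcr-2 (-1.43 ± 0.20). Dcr-2 values do not separate the native gene from the driven transgene, so which of them fell is unknown. CG6762 (-1.39 ± 0.21), Uro, urate oxidase (-1.25 ± 0.25), Kaz1-ORFB (-1.21 ± 0.26), Cyp6d5 (-1.13 ± 0.14), Ama (-1.03 ± 0.14), CG6870 (-1.03 ± 0.14) and CG16727 (-1.0 ± 0.22) completed the list of 12. PGRP-SB2 had values of 0 in many libraries of both diets, and its adjusted p was 0.0404.

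Of 2428 genes tested with limma over 13 control and 13 high-sugar libraries, 412 were higher and 228 lower on high sugar at an adjusted p under 0.05, and of these 640, 599 went the same way in all 3 backgrounds and 428 in all 5 runs. With the run in place of the background as a term, 546 were higher and 315 lower, and all 640 were among them with the same direction. The split depended on scaling and on the filter: after median-of-ratios scaling 262 were higher and 318 lower, after quantile normalization 274 and 300, and with no filter, on 10094 genes, 580 and 1108. Without run 13-21, 1089 genes passed (759 higher), and without run 49-54, 643 (385 higher).

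**Figure D1:**
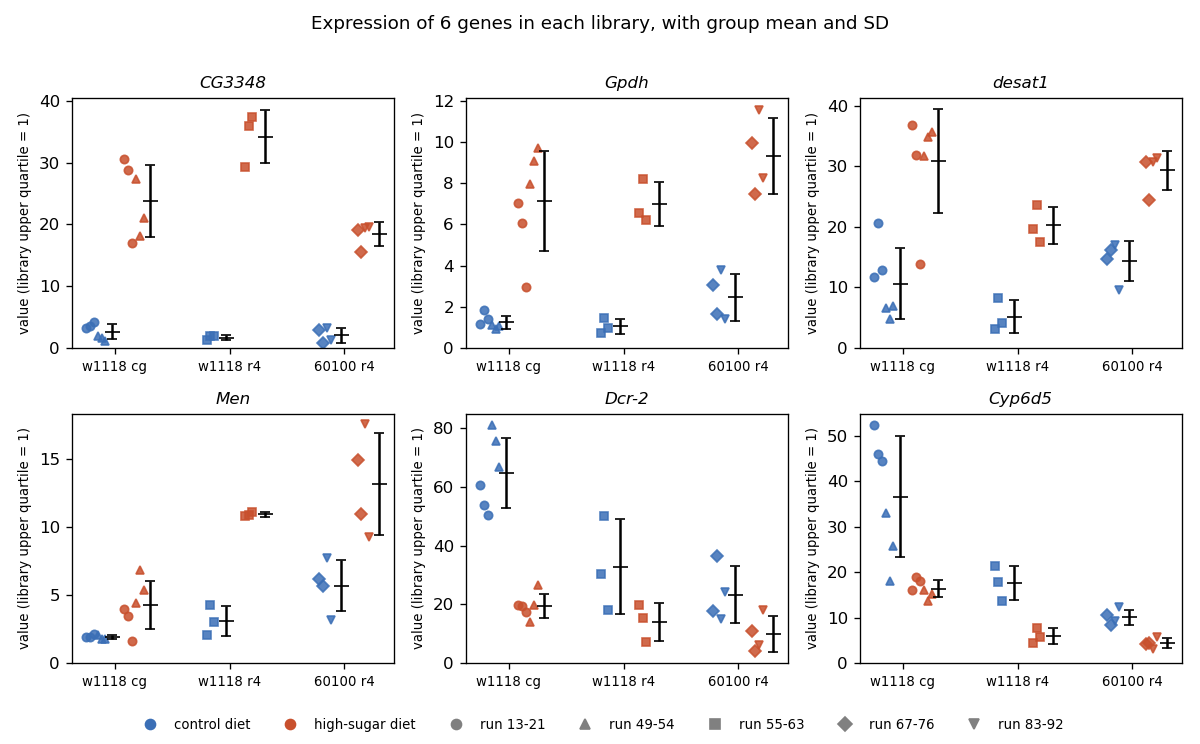
Values of CG3348, Gpdh, desat1, Men, Dcr-2 and Cyp6d5 in each library, on a linear axis in multiples of the library's upper quartile, by background and diet. Points are libraries, marked by run; black bars are the group mean and SD. CG3348 in the high-sugar libraries lies above every control library in all 3 backgrounds.

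In glycolysis 6 of 10 tested genes rose on high sugar and none fell (9 and 0 adjusted over the list alone), among them Pgi (0.70 ± 0.14), Eno (0.61 ± 0.13), Gapdh1 (0.49 ± 0.13) and PyK (0.48 ± 0.08). In the list of gluconeogenesis, glycogen and trehalose 7 of 11 rose (8 adjusted over the list alone), with Tps1, which makes the blood sugar trehalose, at 0.68 ± 0.17, the glycogen branching enzyme CG33138 (AGBE) at 0.61 ± 0.13, the trehalose transporter CG30035 (Tret1-1) at 0.57 ± 0.12 and CG9485 at 0.31 ± 0.08; Pepck (0.51 ± 0.23) did not pass. In the pentose phosphate and NADPH list 4 of 8 rose (7 adjusted over the list alone): Men, malic enzyme (1.05 ± 0.15), Pgd (0.91 ± 0.13), Tal (Taldo, 0.85 ± 0.16) and CG8036 (0.45 ± 0.11). Zw, which opens the pentose phosphate pathway, had 0.21 ± 0.08 with an adjusted p of 0.0518. The camera test gave adjusted p values of 0.00646 for glycolysis, 0.00581 for the trehalose list and 0.00531 for the NADPH list, each 0.519 with an estimated correlation. Without run 49-54, 3 glycolysis genes rose and 1 fell (adjusted p = 0.160), and 4 of 12 genes of the trehalose list rose (0.0729). In that setting only the NADPH list (adjusted p = 0.045), the purine list (0.00529) and the cytosolic ribosomal list (0.0262) passed among all lists.

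Among genes of fat synthesis, AcCoAS, acetyl-CoA synthetase (1.16 ± 0.14), desat1 and CG3523 (FASN1, fatty acid synthase, 0.63 ± 0.15) rose, while HLH106 (SREBP, a regulator of lipid synthesis) fell by 0.21 (-0.21 ± 0.07). With these, 3 of 6 tested members rose and 1 fell, and the same numbers held adjusted over the list alone. The list as a whole had an adjusted p of 0.109, or 0.712 with an estimated correlation. ATPCL, at 0.11 ± 0.11, did not pass. In the list of triglyceride synthesis and lipid droplets 4 of 8 rose (5 adjusted over the list alone): Gpdh, the droplet protein Lsd-1 (0.72 ± 0.12), mdy (0.57 ± 0.12) and CG3209 (0.16 ± 0.05). Its adjusted p was 0.0175, or 0.519 with an estimated correlation, and 0.0768 without run 13-21. Lsd-2 (-0.29 ± 0.13) did not pass. Of 16 genes of lipolysis and fatty acid oxidation 7 rose (8 adjusted over the list alone), including CG9527 (0.58 ± 0.08), scu (0.47 ± 0.12), Arc42 (0.35 ± 0.11) and CG5009 (0.29 ± 0.06), with an adjusted p of 0.0213, or 0.712 with an estimated correlation, and 0.117 after quantile normalization. The lipase gene bmm (-0.01 ± 0.10) did not pass. Both tested genes of coenzyme A synthesis, fbl (0.73 ± 0.20) and Ppat-Dpck (0.49 ± 0.09), rose, with 2 rises adjusted over the list alone; the list was too short for camera.

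Nuclear-encoded genes of the respiratory chain rose for 8 of 27 members (8 adjusted over the list alone), such as RFeSP (0.42 ± 0.12), ND75 (0.37 ± 0.09), CG4769 (0.36 ± 0.07) and ND42 (0.29 ± 0.07), and cytosolic ribosomal proteins for 15 of 77 (4 adjusted over the list alone), such as RpS3A (0.57 ± 0.16), RpL5 (0.57 ± 0.17), RpL11 (0.43 ± 0.12) and RpL23A (0.40 ± 0.10). Their adjusted p values were 0.0167 and 0.00531 (each 0.712 with an estimated correlation), and 0.0541 and 0.856 after quantile normalization. The counts moved as well: 17 of 27 and 54 of 77 rose without run 13-21, but 4 and 5 after median-of-ratios scaling. Of the TCA cycle list only CG11876 (0.28 ± 0.10) rose among 12, none adjusted over the list alone, and of the mitochondrial ribosomal proteins only mRpL28 (0.34 ± 0.12) rose among 12, again none adjusted over the list alone. Their adjusted p values were 0.376 and 0.909. Genes for folding in the endoplasmic reticulum rose for 6 of 11 members (6 adjusted over the list alone), with Crc (calreticulin, 0.70 ± 0.14), Gp93 (0.67 ± 0.16), Xbp1 (0.51 ± 0.10) and CaBP1 (0.45 ± 0.09). That list had an adjusted p of 0.0229, or 0.712 with an estimated correlation, 0.193 without run 13-21 and 0.127 after quantile normalization. Its median change was 0.25 in run 13-21, 0.91 in run 49-54 and 0.3 in run 55-63. In the runs of 60100 r4 the median did not rise, at -0.1 in run 67-76 and -0.07 in run 83-92. The diet effect on Gp93 differed between backgrounds (limma, joint test, adjusted p = 0.0279).

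Genes of purine synthesis and breakdown fell for 5 of 10 members, among them Uro, ade3 (-0.78 ± 0.18), CG3590 (-0.55 ± 0.11) and CG11089 (-0.51 ± 0.13). Adjusted over the list alone 5 fell and 1 rose. The list had an adjusted p of 0.00581 with camera, or 0.519 with an estimated correlation. Uro is also the tested gene of the Malpighian tubule markers, and carry-over of that tissue was not tested. Genes that respond to the moulting hormone ecdysone fell for 4 of 6 members (4 adjusted over the list alone): ImpE2 (-1.39 ± 0.25), br (-0.60 ± 0.14), Eip55E (-0.47 ± 0.12) and Eip75B (-0.39 ± 0.10). Here the adjusted p was 0.0167, or 0.226 with an estimated correlation, and 0.0550 without run 49-54. In amino acid breakdown and one-carbon metabolism Odc1, ornithine decarboxylase, rose by 0.89 ± 0.10, while Nmdmc (-0.87 ± 0.18), Gdh (-0.48 ± 0.16) and Oat (-0.42 ± 0.13) fell; adjusted over the list alone 2 rose and 3 fell among 12 (list adjusted p = 0.202). Among 19 genes of detoxification and oxidative stress, Cyp6w1 (0.94 ± 0.17) and Jafrac1 (0.64 ± 0.11) were among 3 that rose, and Cyp6d5 and the catalase gene Cat (-0.63 ± 0.09) fell, with the same numbers adjusted over the list alone (list adjusted p = 0.791).

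Few signalling genes passed. Of the insulin, FOXO and TOR list only CG11299 (Sesn, -0.37 ± 0.09) fell among 5, also adjusted over the list alone (adjusted p = 0.341), and Thor (-0.38 ± 0.20) and Ilp6 (-0.31 ± 0.18) did not pass. In the list of sugar-responsive transcription factors and targets the zinc finger gene sugarbabe rose by 0.62 ± 0.16 and was the only one of 6, also adjusted over the list alone (adjusted p = 0.434), while cbt (-0.11 ± 0.12) and daw (0.10 ± 0.13) did not pass. Of 9 secreted lipoproteins and hormones CG14375 (CCHa2, 1.17 ± 0.13) rose and CG15917 (Gbp1, -0.76 ± 0.24) fell, as they did adjusted over the list alone (adjusted p = 0.902); NLaz (0.47 ± 0.22) and Rfabg (-0.28 ± 0.31) did not pass. Of 7 larval storage proteins regucalcin rose (0.83 ± 0.16) and Lsp1alpha (-0.84 ± 0.31) and Fbp2 (-0.28 ± 0.10) fell; adjusted over the list alone 2 rose and 3 fell. The storage protein genes had a median change of 0.32 while camera placed the list on the lower side (adjusted p = 0.971). Lsp2 (0.32 ± 0.14) and Fbp1 (-0.34 ± 0.15) did not pass. Of 20 antimicrobial and immune genes IM3 and DptB (0.92 ± 0.33) rose, 1 of them adjusted over the list alone (list adjusted p = 0.216), and Drs had 0.43 ± 0.28. The median of this list was 1.57 in run 49-54 and between 0.00 and 0.08 in the other runs.

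Of 8 heat shock genes Hsp67Bc (-0.92 ± 0.28) and Hsp23 (-0.65 ± 0.20) fell, also adjusted over the list alone (list adjusted p = 0.0900). Of 9 genes of autophagy and the lysosome Cp1 (0.36 ± 0.12) and CG10992 (0.34 ± 0.11) rose and Atg7 (-0.37 ± 0.09) fell, as adjusted over the list alone (adjusted p = 0.906). Of 10 extracellular matrix genes LanA (-0.38 ± 0.11), LanB1 (-0.33 ± 0.11) and Ndg (-0.19 ± 0.06) fell, as adjusted over the list alone (adjusted p = 0.207). No gene of the DNA replication list reached the filter, and of ribosome biogenesis only Nop60B did (-0.04 ± 0.08). CG11198 (ACC), Hex-C, ImpL3, InR and upd2 lay below the filter.

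Markers of other tissues moved with the diet in some runs. None of 12 midgut genes passed over all libraries, but their median change was -1.19 in run 49-54, -1.58 in run 55-63, 1.13 in run 67-76 and 1.18 in run 83-92. None of 9 salivary gland genes passed, with medians of 0.73 in run 13-21 and -2.76 in run 49-54. Haemocyte genes fell for 3 of 4 members (3 adjusted over the list alone; adjusted p = 0.0167, or 0.519 with an estimated correlation), with a median of -1.74 in run 49-54 and -0.14 in run 13-21. Of 6 muscle genes 1 rose, also adjusted over the list alone (adjusted p = 0.711), with medians of 1.12 and 0.83 in the runs of 60100 r4. Epidermis and cuticle genes had no call among 5 (adjusted p = 0.711), with medians of -1.37 in run 13-21, 0.97 in run 67-76 and 0.52 in run 83-92. Among 12 fat body genes 2 rose and 2 fell, as adjusted over the list alone (adjusted p = 0.971), with medians of 0.69 in run 49-54 and -0.51 in run 67-76. Of neuron and glia, Malpighian tubule and ring gland lists 1 gene each was tested; those of the last 2 passed, at -1.25 for the tubule list, which is Uro, and 1.22 for sad, an enzyme of ecdysone synthesis. No gene of the germline and ovary, testis, imaginal disc, trachea or oenocyte lists reached the filter.

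**Figure D2:**
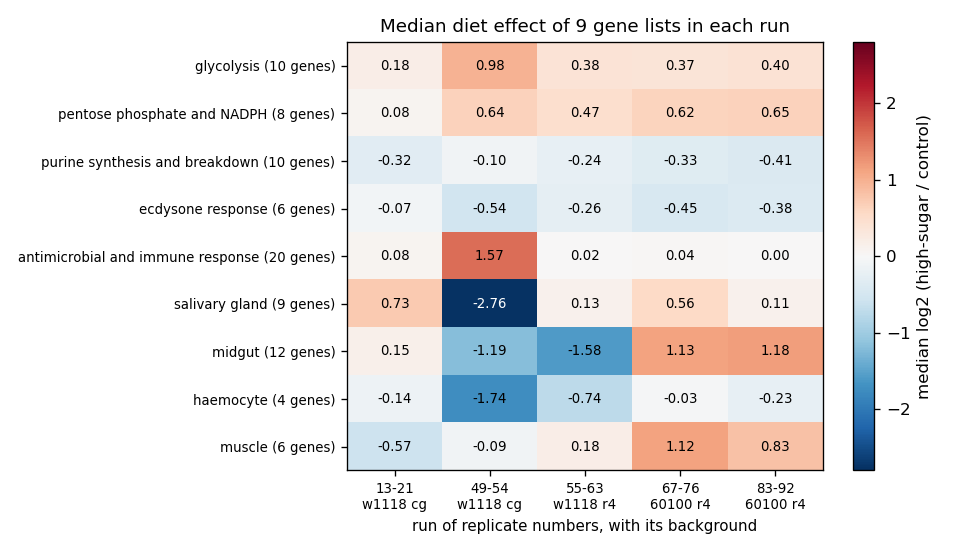
Median log2 change, high-sugar over control, of the tested genes of 9 lists (rows) in each run of replicate numbers (columns, with the background); colour and printed number give the median. The midgut row is negative in runs 49-54 and 55-63 and positive in runs 67-76 and 83-92, while the glycolysis row is positive in all 5 runs.

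The next comparison asked whether each background alone showed the diet change. CG3348, Gpdh and desat1 rose in all 3 backgrounds, Gpdh by 1.8 log2 units in w1118 cg, 1.97 in w1118 r4 and 1.62 in 60100 r4, and desat1 by 1.53, 1.86 and 1.01. Dcr-2 fell by 1.68 in w1118 cg, and its change was -1.16 in w1118 r4 and -1.27 in 60100 r4. With limma, 194 genes were higher and 92 lower in w1118 cg, 165 and 48 in w1118 r4, and 201 and 134 in 60100 r4. In w1118 r4 and 60100 r4 together 74 genes were higher in both and 17 lower in both, against 13.7 and 2.6 for independent lists. For w1118 cg with w1118 r4 these numbers were 55 and 11 (13.2 and 1.8 if independent), and for w1118 cg with 60100 r4 52 and 19 (16.1 and 5.1). The groups compared share no libraries, but the spread of each gene was estimated over all 26 samples. Genes with a small spread can thus pass in several backgrounds together, so the numbers for independent lists are not those expected by chance. Genes called in opposite directions numbered 0, 2 and 5 for these pairs of backgrounds, in the order given. Rescaling moved these splits: median-of-ratios scaling gave 177 higher and 150 lower in w1118 cg and 85 and 77 in w1118 r4, and quantile normalization gave 81 and 103 in 60100 r4. With no filter 250 were higher and 649 lower in w1118 r4 and 525 and 774 in 60100 r4, where 114 of 270 genes were higher with the pseudocount of 0.1. Without run 49-54, 41 were higher and 119 lower in w1118 cg.

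The 2 runs of w1118 cg differed. In a contrast of each run alone 41 genes were higher and 128 lower in run 13-21, but 575 and 236 in run 49-54, and the difference between the runs passed for 497 genes. The side of this difference depended on scaling: run 49-54 lay above run 13-21 for 368 of these and below for 129, but for 106 and 330 genes after median-of-ratios scaling and 236 and 174 after quantile normalization. The correlation of log2 changes across 2428 genes, which are not independent replicates, was 0.14 between these runs and 0.75 between the runs of 60100 r4, where 0 genes differed (54 at an unadjusted p under 0.05, limma). The close pairs 67 with 83 (correlation 0.991) and 75 with 91 (0.990) each span the runs of 60100 r4. The agreement of those runs may therefore not be independent, and it was not computed with the pairs averaged. With the background as a term, the 213 genes of w1118 r4 fell to 85 without high-sugar replicate 62, and the 335 of 60100 r4 to 120 without high-sugar replicate 91 and to 86 with replicates 67 and 83, and 75 and 91, the closest pairs, averaged. With the run as a term and all libraries, 463 genes passed in w1118 cg, 430 in w1118 r4 and 631 in 60100 r4.

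The interaction tests asked whether the diet change differed between backgrounds. The gene sad stood at 2.95 ± 2.56 (SD, n = 4) on the control diet and 33.4 ± 8.75 (n = 4) on high sugar in 60100 r4, with a log2 change of 3.26, against 1.05 in w1118 r4 and -0.05 in w1118 cg. This gene is also the tested gene of the ring gland markers, and carry-over of that tissue was not tested. The gene obst-J changed by 2.33 in 60100 r4, 1.1 in w1118 r4 and 0.03 in w1118 cg, and 7B2 by 1.3, 1.39 and -0.39. CoII and CoI, both of the mitochondrial genome, changed by 4.11 and 2.47 in w1118 r4, by 0.48 and 0.05 in 60100 r4 and by -0.39 and -0.20 in w1118 cg. Other transcripts of that genome had smaller changes in w1118 r4, with CoIII at 0.76, Cyt-b at 0.47, ND4 at 0.12 and ATPase6 at -0.02. CG1702 (GstT3) changed by 0.72 in 60100 r4, 0.15 in w1118 r4 and -0.43 in w1118 cg. In the joint limma test of the 3 backgrounds 95 genes passed, led by obst-J (adjusted p = 4.33e-07) and sad (2.07e-05). The diet effect of w1118 cg lay above that of w1118 r4 for 4 genes and below it for 34, led by CoII, Arc2, 7B2, CoI and CG4325; median-of-ratios scaling gave 6 and 22, no filter 121 and 55, and leaving out run 13-21 gave 80 and 96. The diet effect of 60100 r4 lay above that of w1118 r4 for 4 genes, among them obst-J (1.23 ± 0.23) and sad (2.22 ± 0.42). It lay below for 8, among them CG2947 (-0.88 ± 0.17). Median-of-ratios scaling gave 4 and 4, no filter 51 and 28, and the pseudocount of 0.1 gave 1 and 14, with obst-J at -0.40. In control w1118 r4 obst-J stood at 0.0414 and sad at 0.223, where the added 1 understates changes. The side on which such genes lie can therefore depend on the pseudocount. The set of stock interaction genes fell to 0 without high-sugar w1118 r4 replicate 62. It also fell to 0 with the marker means of salivary gland and midgut as covariates (limma).

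The driver comparison set w1118 cg beside w1118 r4, averaged over the diets. Transcripts of the mitochondrial genome were far higher in w1118 cg: CoIII by 5.59 ± 0.38 log2 units, Cyt-b by 5.0 ± 0.27, ATPase6 by 4.40 ± 0.25 and ND4 by 4.27 ± 0.18, with all 11 tested genes of that genome higher and a median of 4.05. The feature noncoding_25217 was also higher, by 4.68 ± 0.42. Lowest in w1118 cg relative to w1118 r4 were PGRP-SC2 (-2.90 ± 0.32), CG14752 (-2.86 ± 0.17), listed at 0 in every w1118 cg library, inx7, a gap junction gene (-2.72 ± 0.15), and nAcRbeta-21C, a subunit of acetylcholine receptors (-2.68 ± 0.13). With limma 653 genes were higher and 737 lower, 823 and 603 after median-of-ratios scaling, and 2056 and 1716 with no filter. Of 9 salivary gland genes 5 were higher (5 adjusted over the list alone), with a median of 2.18 (list adjusted p = 0.0930). The columns of these backgrounds had been scaled in separate sets before deposit, and the driver goes with the run, so levels are not on a common scale and driver and run cannot be told apart.

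The comparison of male stocks set 60100 r4 beside w1118 r4. The lysozyme genes LysD (3.58 ± 0.29) and LysB (3.48 ± 0.31), Arc1 (3.46 ± 0.16), CG10102 (3.32 ± 0.14) and the glue gene Sgs5 (3.29 ± 1.31) were higher in 60100 r4. Sgs5 passed narrowly (limma, adjusted p = 0.0414) and is a salivary gland marker. Of 9 salivary gland genes 1 was higher, 0 adjusted over the list alone and 0 after median-of-ratios scaling. Carry-over of that tissue was not tested for this comparison. Lower were CoI (-3.01 ± 0.23), the ribosomal protein gene RpL38 (-2.99 ± 0.41), CoII (-2.67 ± 0.31), noncoding_1263 (-2.10 ± 0.32) and a predicted transcript without a gene symbol (-1.92 ± 0.16). CoII stood at 1.76 ± 0.970 (SD, n = 4) in 60100 r4 and 3.93 ± 1.52 (n = 3) in w1118 r4 on the control diet, but at 3.19 ± 2.59 and 89.7 ± 43.9 on high sugar. RpL38 stood at 0.669 ± 0.300 and 4.83 ± 2.56 on the control diet and at 3.55 ± 4.90 and 61.3 ± 11.05 on high sugar. The median of 11 genes of the mitochondrial genome was -0.35. Epidermis and cuticle genes were higher for 5 of 5 members (5 adjusted over the list alone) with a median of 2.98, and muscle genes for 4 of 6 (5 adjusted over the list alone), though camera gave adjusted p values of 0.201 and 0.218. The lists that passed camera were glycolysis (8 of 10 higher, adjusted p = 0.0226), NADPH (7 of 8, 0.0154), respiratory chain (18 of 27, 0.0154) and cytosolic ribosomal proteins (54 of 77, 1 lower, 0.00389), with 9, 8, 20 and 58 higher adjusted over each list alone. Each had 0.987 with an estimated correlation, and after quantile normalization the ribosomal list had 10 higher and 14 lower (adjusted p = 0.822). Under 3 rescalings the epidermis list passed as well, at 0.0171 to 0.0236. After quantile normalization the muscle list passed (0.0371), and on the common upper quartile the insulin, FOXO and TOR list did (0.0332), with 4 of 6 genes lower and 4 adjusted over the list alone. These calls used the preset correlation. As deposited, the epidermis, muscle and insulin lists each had 0.987 with an estimated correlation, which was not computed after rescaling. With limma 987 genes were higher and 199 lower, but once each library was divided by an upper quartile over common features 563 were higher and 537 lower, and 512 and 485 after median-of-ratios scaling. The median over all genes was 0.262 as deposited and 0.014 on the common upper quartile, and stock and run cannot be told apart.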

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

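The tests of exchanged labels, tissue carry-over, the scaling of mitochondrial transcripts, library preparation, fat body share and sample splits were chosen only after the results were seen; the tests of the scaling behind the run difference and of fewer mitochondria were written before theirs.

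The diet effect differed between backgrounds by the joint test for 16 named genes. Adjusted p values were 4.33e-07 for obst-J, 2.07e-05 for sad, 0.000145 for CG1702, CoII and 7B2, 0.00034 for Arc2, 0.00144 for CoI and CG15067, 0.00247 for CG4325 and 0.00937 for CG2947. They were 0.0115 for Eip55E, 0.0144 for Cp1, 0.0152 for CG15068, 0.0163 for a predicted transcript without a gene symbol, 0.0279 for Gp93 and 0.0386 for Cyp4e3.

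Single libraries lay far from the rest of their group in 53 of 600 combinations of gene and group tested, where chance flags about 1 in 20. The w1118 r4 groups (n = 3) were too small for this check and were left out of it. Each number here is the gap to the nearest library over the whole range. Control 60100 r4 replicate 68 stood apart for 14 genes: PGRP-SC2 (0.956), sad (0.949), CG31775 and CG42586 (0.941), sugarbabe (0.939), ATPCL (0.937), Pepck (0.928), IM3 (0.925), LysD (0.924), CG14752 (0.915), CG7998 (0.852), CG15067 (0.846), LanA (0.837) and cbt (0.832). High-sugar 60100 r4 replicate 76 did so for 15: IM2 (0.996), that predicted transcript (0.977), RpL5 (0.941), CG15068 (0.930), RpL38 (0.906), CoIII (0.903), desat1 (0.885), CG31775 and CG42586 (0.884), CG7998 (0.868), ATPase6 (0.865), CG3348 (0.856), l(1)G0334 (0.840), CG10992 (0.834) and IM10 (0.830). In both groups the other 3 libraries include a closely similar pair, which raises such ratios. In 60100 r4 ND4 stood apart in control replicate 67 (0.843) and nAcRbeta-21C in high-sugar replicate 91 (0.925). In control w1118 cg, replicate 14 stood apart for obst-J (1.0), LysD (0.833), l(1)G0334 (0.821), CG8036 (0.801), CG3523 (0.645) and Cyp6w1 (0.634), and replicate 51 for mRpL28 (0.688) and Zw (0.650). In high-sugar w1118 cg, replicate 53 stood apart for CG15067 (0.869), DptB (0.853), mRpL28 (0.794), CG10992 (0.707) and IM10 (0.659), and replicate 21 for desat1 (0.775), CG11299 (0.756) and fbl (0.690). In that group replicate 20 stood apart for sad (0.847) and PGRP-SB2 (0.781), replicate 52 for sugarbabe (0.690) and Lsd-1 (0.631), replicate 19 for LysD (0.689) and replicate 54 for Arc2 (1.0).

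The diet effect of w1118 cg differed between runs 13-21 and 49-54 for 497 genes. The scaling before deposit is argued against as the source of that number, since at least 410 genes differed under each of 3 rescalings, though it decides on which side most of them lie (368 and 129 as deposited, 106 and 330 after median-of-ratios scaling). Exchanged diet labels in run 13-21 are argued against too, since 78.0 percent of 91 genes called the same way in both r4 backgrounds kept that direction there. With salivary gland and midgut marker means as covariates 37 genes differed, but the median size of the difference only went from 1.0 to 0.80 while its median SE rose from 0.24 to 0.35, so carry-over of these tissues may account for part and stays open. No biological explanation was tested, as the labels give the runs no meaning.

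Transcripts of the mitochondrial genome were higher in w1118 cg than in w1118 r4 by a median of 4.05 log2 units. The scaling before deposit is argued against, since the median was 3.94 on a common upper quartile. Fewer mitochondria in w1118 r4 were predicted to raise the median of 27 nuclear-encoded respiratory chain genes, which was -0.01. Nuclear transcripts do not measure the number of mitochondria, so this test cannot decide that explanation. A difference in library preparation may also be the source, and cannot be told apart from the driver, because 0 runs hold both drivers.

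Midgut markers were lower on high sugar in runs 49-54 and 55-63 and higher in runs 67-76 and 83-92, for 100 percent of the 12 tested markers in each of these runs, while 25 percent were lower in run 13-21. A changed share of fat body alone is argued against, since in run 49-54 the medians of the midgut, salivary gland, muscle and haemocyte lists lay up to 2.67 log2 units apart. Midgut tissue carried over in different amounts may remain the source, and cannot be told apart from a diet effect on these genes within fat body, because the markers that showed the pattern are the only ones it was tested on.

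Other splits of the libraries into groups of the same sizes were counted for each comparison. For diet across backgrounds 1 of 100 splits, the real one, gave 640 genes, and the highest other gave 3. With the close pairs 67 with 83 and 75 with 91 averaged, the real split gave 505 genes, 1 of 100, and the highest other 89, so chance can be excluded. For the joint interaction test 3 of 100 splits gave at least the real 95 genes, the highest other 278. With the run as a term it was 3 of 100 (312 genes, highest other 522), and with the pairs averaged 4 of 100 (42 genes, highest other 229). These shares are under 0.05, but only narrowly, and some other splits gave far more genes than the real one. They do not settle whether chance can be excluded for the joint interaction.

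In 60100 r4 the real split gave 335 genes, 1 of 35 splits, and the highest other 62. This counts the close pairs as separate samples. With them averaged, the 10 splits are too few for a share under 0.05 (86 genes, 1 of 10, highest other 4), and so are the 10 splits of w1118 r4 (213 genes, 1 of 10, highest other 1). Chance cannot be excluded for the interaction with male stock (12 genes, 5 of 100, highest other 490; with the run as a term 90 genes, 8 of 100, highest other 636). The interaction with driver lay near the bound, at 6 of 100 (38 genes, highest other 266). With the run as a term it was 4 of 100 (124 genes, highest other 423). These shares lie close together on both sides of 0.05, so chance is not excluded for this interaction under either model. In w1118 cg, splits that ignore the runs reached the real 286 genes in 8 of 100, the highest other 775. Splits with many more genes than the real one point to a structure of the samples: a split of w1118 cg by run gave 1177 genes. With the run as a term and diet permuted within runs, the real split gave 463 genes, 1 of 100, and the highest other 151, so chance can be excluded there once the runs are taken into account.

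Drivers and male stocks differ by whole runs. Splits of single libraries gave as many genes in 1 of 100 for the driver difference (1390 genes, highest other 498) and in 1 of 100 for the male stock difference (1186 genes, highest other 686), but they ignore the runs. By whole runs there are 3 splits each, too few for a share under 0.05. For the driver 2 of 3 gave at least 1390 genes, the other being run 13-21 set against runs 49-54 and 55-63 with 1564, and for the male stock 1 of 3 gave 1186 and both others 0 (limma; 550 and 455 at an unadjusted p under 0.05).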

How the results depend on the processing

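The common upper quartile, leaving out runs, averaged pairs, marker covariates, and run as a term in interactions were chosen only after the results were seen. Counts are listed as diet across backgrounds, w1118 cg, w1118 r4, 60100 r4, joint interaction, driver interaction, stock interaction, driver difference and stock difference, as far as they moved by over 1.5 times. As reported they were 640, 286, 213, 335, 95, 38, 12, 1390 and 1186. With no filter on 10094 genes, all but w1118 cg moved: 1688, 899, 1299, 411, 176, 79, 3772 and 3117. With a mean of at least 5, on 766 genes, they were 251, 124, 92, 85, 32, 20, 7, 463 and 407. These 2 settings change the number of genes tested. For the other settings the cause was not tested. Run as a term gave 463, 430, 631, 312, 124 and 90 from w1118 cg to the stock interaction. Without run 13-21 the first 7 were 1089, 779, 504, 705, 472, 176 and 115, and without run 49-54 those from w1118 cg on were 160, 502, 703, 370, 251 and 123, with 3 lists passing in place of 11. Robust fits gave 878 in w1118 r4, 990 in 60100 r4 and 516, 132 and 452 for the interactions. Fits on 1 background gave 98 in w1118 cg and 328 in w1118 r4. Diet across backgrounds was 358 without w1118 r4 and 278 without 60100 r4. In 60100 r4 median-of-ratios scaling gave 206, quantile normalization 184 and averaged pairs 86. Averaged pairs gave 42 for the joint and 1 for the stock interaction, quantile normalization 19 for the latter and 7 lists, and covariates 121 in w1118 r4 and 0 for the stock interaction (limma). An estimated correlation left 0 lists. Leaving out 1 replicate gave 547 to 702 across backgrounds, 182 to 366 in w1118 cg, 85 to 245 in w1118 r4, 120 to 511 in 60100 r4, 57 to 157, 19 to 48 and 0 to 23 for the interactions, 1227 to 1443 for the driver and 1045 to 1215 for the stock. The lowest values came without high-sugar 60100 r4 replicate 91 (547, 120, 57), high-sugar w1118 cg replicate 52 (182) and high-sugar w1118 r4 replicate 62 (85, 19, 0). High-sugar 60100 r4 replicate 92 raised the counts when left out (511, 157, 23), and leaving out any replicate of w1118 r4 lowered its own count by over 1.5 times, as did control replicates 67 and 84 and high-sugar replicates 75 and 76 in 60100 r4. Among named genes 1 value reversed, obst-J in the stock interaction with a pseudocount of 0.1 (-0.40). None of them reversed under the 3 rescalings. Depth is unknown, so its limit cannot be given. In w1118 r4 fewer features were above 0 on high sugar than on the control diet. Whether this bears on the counts with no filter was not tested.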

Other observations

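Values in this part belong to no comparison above, and no hypothesis is attached to them. The largest component of variation over the 26 libraries took 50.9% of the variance and the next 17.9%. Replicates of 1 run in w1118 cg correlated at 0.942 to 0.974 on the control diet, and across its 2 runs at 0.820 to 0.918. On high sugar these ranges were 0.953 to 0.978 and 0.763 to 0.844.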
